A study of Arabidopsis thaliana with 36 samples.

How the data were processed

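RNA from mature rosette leaves and roots of 3 Arabidopsis genotypes at 2 Pi levels was sequenced in 36 libraries, 3 per group. Plants grew in hydroponic solution with 200 µM Pi and were then kept at 200 µM or 0 µM Pi for 24 h, per the labels' protocols. Libraries were made from poly(A)-selected RNA with a dUTP second strand, per the labels' protocols. All libraries carry the same batch label, so no batch could be compared. Reads were trimmed with Trimmomatic, aligned with HISAT2 2.2.1 to the TAIR10 genome and compared with DESeq2, per the submitters' processing notes. The tool and the strand setting used to count reads, the gene models and any filter are not given in the sources used here.

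The labels do not name the unit of the deposited values per library, and the values show that they are FPKM: fragments or reads assigned to a gene, scaled by its coding length in kb and by the library's total. Multiplied by the coding length in kb, the values of a library summed to between 974170 and 1016900. Low values were whole multiples of 1 read's worth within 0.1 read in 95.2% to 100.0% of cases per library, which gave the depth per library. For each Pi response the deposited table also holds a ratio, which equals the ratio of the authors' group means within 0.013, and the authors' adjusted p-value, whose method of adjustment is not given in the sources used here. The deposited ratio runs 200 µM over 0 µM in WT leaf and 0 µM over 200 µM in the other 5 blocks, per the file headers, and directions are given here as 0 µM against 200 µM throughout. These ratios and p-values were set beside the results and entered no test.

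The table held 27444 genes, all of which matched a locus in a name table of the assembly TAIR10.1, used only for names and for which genes are neighbours, since the files use TAIR10. 3177 genes were at 0 in every library. Values per library served as deposited, on the scale log2(FPKM + 1). In each organ, genes with a mean of at least 1 FPKM over its 18 libraries entered 1 limma fit (version 3.58.1, with trend) with a mean for each of the 6 groups. The 9 comparisons per organ were the Pi response of each genotype, KO and OE against WT at each Pi level, and the difference of each line's Pi response from that of WT. A gene passed at an adjusted p under 0.05 (limma, Benjamini-Hochberg within a comparison). SPX3 and IPS1 fell below the filter in leaf, with means of 0.227 and 0.218 FPKM. Leaf against root was tested only as a difference between organs of the lines' effects over 15608 genes, where 274 differed for KO and 66 for OE at 200 µM and 1 for each at 0 µM.

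The comparisons, the threshold, the gene lists, the rule for named genes and most other settings tried were set before the data were examined. The plan assumed read counts, and since the values are FPKM the alternatives planned for counts and for a table of the authors' comparisons alone were not run. The 21 lists held 403 genes fixed by locus: Pi starvation signalling and Pi transport, Pi signalling regulators, membrane lipid remodelling, acid phosphatases and RNases, nitrate and ammonium uptake, NIGT1 and LBD nitrogen regulators, potassium uptake, iron deficiency, iron storage, anthocyanin and flavonoid synthesis, 26S proteasome, autophagy, photosynthesis, root tissue markers, salicylic acid, jasmonate, heat shock, cold, drought and abscisic acid, circadian clock, cell cycle, and senescence and starvation. The name table matched 375 members by name, held no contradicting name for the other 28, and 0 were dropped. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 189 tests of an organ. Fry asks whether a list's genes move on balance in 1 direction and does not compare the list with other genes.

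Named genes followed a rule: per Pi response or line comparison the 5 largest rises and 5 largest falls among genes that passed with a mean log2 value of at least 1 and no overlap between the groups, for interactions the 3 largest each way, up to 2 risers and 2 fallers with the smallest adjusted p per list, and 9 marker genes in each comparison. The text names them as far as room allows, and NRT2.1 is not described. The PPSR1 locus, first in the rule, could not be identified from the files or the name table and was not analysed here. Genes that share 31-base words of coding sequence with another gene are called uncertain where named, since the files do not say how shared reads were counted.

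The fit was tested on simulated data with 100 genes each changed 2-fold and 4-fold. In the Pi response of WT leaf 21% of 2-fold and 83% of 4-fold changes were recovered, in KO leaf against WT at 200 µM 27% and 83%, and in the KO interaction in leaf 3% and 49%. In root the shares were 47% and 89%, 45% and 92%, and 7% and 77%. Depth was between 2700000 and 13200000 reads per library, and PCR copies were not marked, so depth covers counting error only. Pairs of libraries of a group differed by more than read sampling, with a chi-square per gene between 6.73 and 124 over 36 pairs.

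Alternatives planned before were the groups of a comparison alone, replicate number as a block, each library left out in turn, 0.1 added in place of 1, no filter and limma without trend. Median-of-ratios scaling was planned for the list tests. Chosen after the data were seen were this scaling for genes and their counts, voom on the recovered reads, leaving out the library of each organ farthest from its group (KO replicate 1 at 200 µM in leaf, WT replicate 2 at 200 µM in root), an additive term for each library's level of long genes, and the list tests with 0.1 added, no filter, no trend, the long-gene term and each library left out. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used. Raw reads were not used here.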

Results

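Messenger RNA was measured by strand-specific RNA-seq of poly(A)-selected RNA from mature rosette leaves and roots of Arabidopsis thaliana in hydroponic culture. The 3 genotypes were the wild type Columbia-0 (WT), a T-DNA knockout of PPSR1 (KO) and a line that overexpresses AtPPSR1 (OE). Phosphate (Pi) was supplied at 200 µM or at 0 µM for the last 24 h before harvest. The 12 combinations of genotype, Pi level and organ held 3 libraries each, 36 in all, which the labels describe as independent biological replicates. The series title names deficiency of nitrogen, phosphorus and potassium, and among these nutrients only Pi was varied in the libraries used here. Gene levels are FPKM, given as mean ± SD over n = 3 libraries. Changes are log2 changes of FPKM + 1 with their standard error (SE), as 0 µM against 200 µM or as a line against WT, and adjusted p is from limma with Benjamini-Hochberg adjustment. A number in parentheses directly after a gene or its locus is its log2 change. The log2 scale with 1 added understates changes of genes at low FPKM. 21 gene lists were tested as sets with limma's camera at a preset correlation, and of the 126 set calls 3 hold with an estimated correlation: Pi starvation in OE root, and senescence and starvation in KO root and OE root, each in the Pi response. With a single library left out, 57 of the 126 lost the call at the preset correlation. Not every call is described. Where a list's adjusted p is given below, its values without a library that lost the call follow.

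The depth recovered from the values was between 6670000 and 13200000 reads per leaf library (median 10800000) and between 2700000 and 11800000 per root library (median 6240000). KO root replicates 1 and 2 at 0 µM had the lowest depths, at 2700000 and 3260000 reads. In leaf 16489 genes were tested and in root 19166. KO leaf replicate 1 at 200 µM stood apart, with 9488 genes at 0 where the other leaf libraries had 7353 to 8551. Libraries also differed in the level of genes with coding sequences over 4000 bases. In root, the median of these 243 genes lay at -1.23 (log2) from the middle of the organ's libraries in WT replicate 2 at 200 µM and at -0.47 in WT replicate 3 at 200 µM, with the others between -0.21 and 0.38. In leaf, the median of 107 such genes lay at -1.25 in WT replicate 2 at 200 µM, -1.04 in OE replicate 1 at 0 µM and -0.88 in WT replicate 1 at 0 µM, with the others between -0.44 and 0.69.

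**Figure D1:**
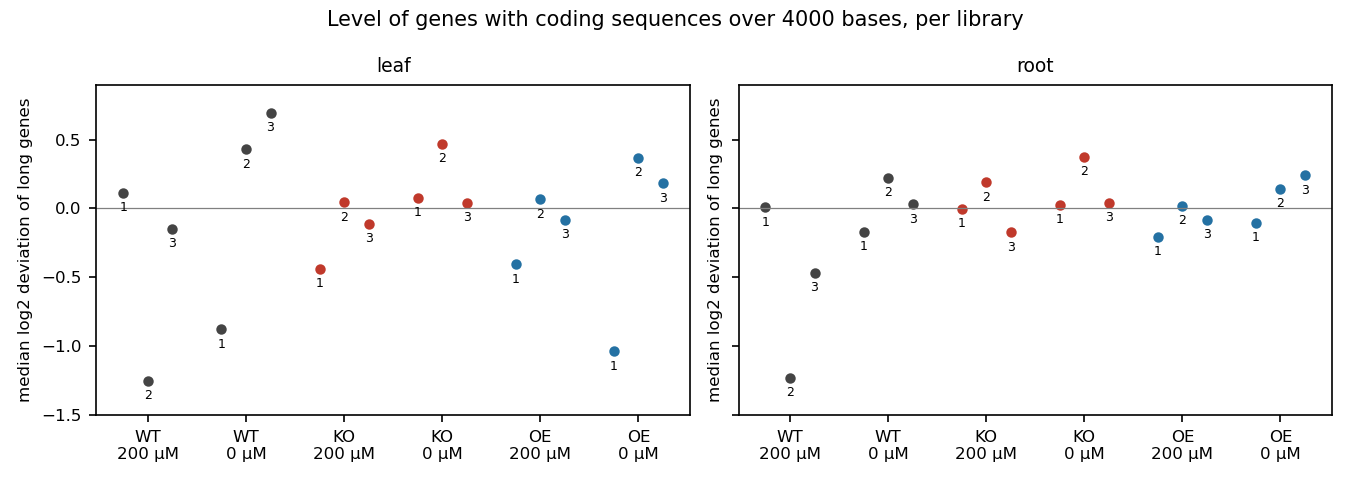
Median log2 deviation, from the middle of the organ's libraries, of genes with coding sequences over 4000 bases in each leaf and root library, numbered by replicate. WT replicate 2 at 200 µM is the lowest library in both organs, at -1.25 in leaf and -1.23 in root.

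The gene targeted in KO and OE comes first. Neither the deposited table nor the name table attaches the name PPSR1 to a locus, so its level was not analysed here and could not check the genotype labels. 4 genes differed from WT in the same direction in both lines, in both organs and at both Pi levels. MRD1 (AT1G53480), annotated as mto 1 responding down 1, averaged 33.3 ± 2.5 FPKM in WT leaf and 41.9 ± 19.6 in WT root at 200 µM, and was listed at 0 in the KO libraries of both groups. In OE leaf at 200 µM it stood at 0.47 ± 0.262. AT3G01345, annotated as an expressed protein, was listed at 0 in KO leaf at 200 µM against 75 ± 11.9 in WT, and fell by 6.18 on the log2 scale in OE leaf. AT1G75945, a hypothetical protein, and AT2G21185, a transmembrane protein, showed the opposite pattern: both were listed at 0 in WT root and averaged 43.1 ± 12.8 and 23.2 ± 9.65 FPKM in KO root, and 39.8 ± 4.11 and 23.5 ± 4.65 in OE root, at 200 µM. In leaf at 0 µM their log2 changes were 3.91 ± 0.50 and 5.6 ± 0.35 in KO and 4.15 ± 0.50 and 5.48 ± 0.35 in OE. The adjusted p of the 4 genes lay between 1.43e-13 and 0.00449 over the 8 comparisons, and no loss of 1 library ended a call. AT1G75945 lost the call in KO leaf at 200 µM with the libraries of the comparison's groups alone and in all 4 leaf comparisons with voom, and AT2G21185 with voom in leaf and root of OE at 0 µM.

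DOT1 (AT2G36120), a glycine-rich protein gene, separated the lines. In KO it fell by 6.33 (SE 0.48, adjusted p = 1e-06) in leaf and by 7.2 (SE 0.29, adjusted p = 3.58e-11) in root at 200 µM, from 159 ± 15.1 to 1.06 ± 0.748 and from 949.8 ± 296 to 5.27 ± 0.443 FPKM, and none of the 12 KO libraries reached the lowest WT library. At 0 µM its log2 changes in KO were -7.26 ± 0.48 in leaf and -7.92 ± 0.29 in root. In OE root it fell by 3.43 at 200 µM and by 3.75 at 0 µM, to 88.2 ± 30.4 and 86.8 ± 26.3 FPKM, while its log2 changes of 0.66 and 0.53 in OE leaf did not pass the test. The difference between leaf and root in the effect of OE was 4.09 at 200 µM (adjusted p = 0.000878) and 4.28 at 0 µM (adjusted p = 0.00074). CYP97B3 (AT4G15110), a cytochrome P450, was higher in both lines in leaf at 0 µM, at 43.4 ± 4.82 in KO and 40.1 ± 5.58 in OE against 8.72 ± 0.34 FPKM in WT (adjusted p = 6.95e-06 and 1.97e-05). With limma, 0 genes passed in opposite directions in KO and OE against WT in any of the 4 settings of organ and Pi, and 0 with median-of-ratios scaling. Unchanged groups that share the WT libraries also gave 0 in each of 100 simulated draws, so a count of 0 does not tell the lines apart from no change. At an unadjusted p under 0.05 in both lines, 0 genes ran opposite ways in leaf at either Pi level, 2 in root at 200 µM and 4 in root at 0 µM.

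**Figure D2:**
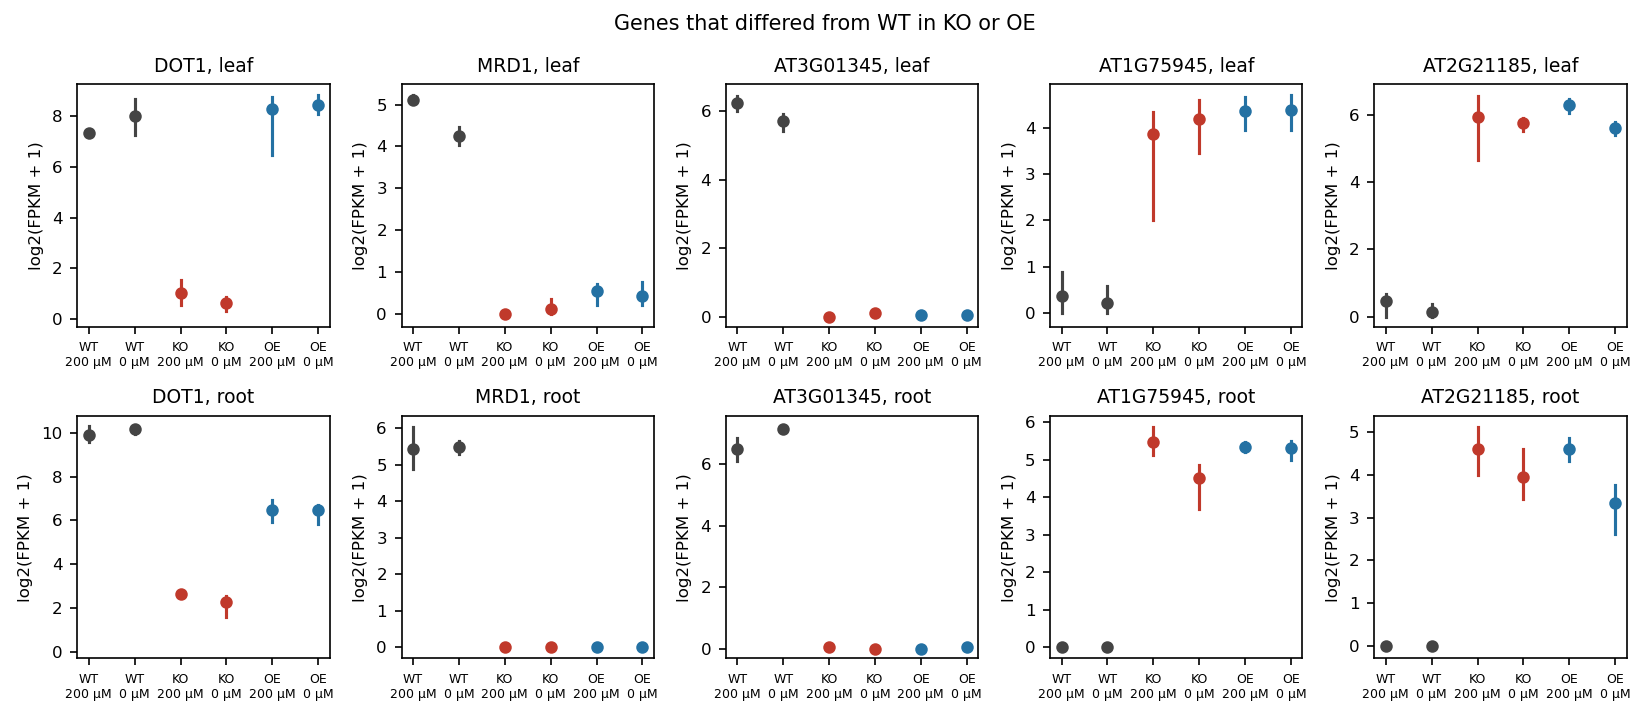
Group means, as log2(FPKM + 1), of DOT1, MRD1, AT3G01345, AT1G75945 and AT2G21185 in WT, KO and OE at both Pi levels in leaf and root, with bars from the lowest to the highest of 3 libraries. In root at 200 µM, AT1G75945 was listed at 0 in WT and averaged 43.1 FPKM in KO and 39.8 in OE.

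The Pi response of leaves, 0 µM against 200 µM within a genotype, asks what 24 h without Pi changed in each line. In KO leaf, genes of the Pi starvation response rose together. SPX1 (AT5G20150), a Pi-sensing SPX protein, rose by 3.41 ± 0.37, from 7.02 ± 2.1 to 85.3 ± 25.3 FPKM, and AT4 (AT5G03545), a noncoding RNA of the Pi starvation response, from 2.99 ± 2.71 to 83.9 ± 56.4. Of the 10 measured members of the list of Pi starvation signalling and Pi transport, 6 rose and 0 fell (7 and 0 adjusted over the list alone), and the list moved up as a set. Pi starvation genes as a set had adjusted p = 1.03e-07, and adjusted p = 0.259 with an estimated correlation. PHO1;H1 (AT1G68740), a Pi exporter homologue, was among the risers, from 1.71 ± 0.842 to 13 ± 5.82. Of 11 genes of membrane lipid remodelling, 6 rose (6 adjusted over the list alone). As a set, lipid remodelling genes had adjusted p = 5.08e-07, and adjusted p = 0.33 with an estimated correlation. They included MGD3 (AT2G11810), a galactolipid synthase, with a log2 change of 2.78, and the sulfolipid synthesis genes SQD1 (AT4G33030, 1.94) and SQD2 (AT5G01220, 1.64). Among 10 acid phosphatases and RNases 3 rose (3 adjusted over the list alone), among them PAP17 (AT3G17790), from 14.9 ± 9.67 to 80.5 ± 21.5, and PAP12 (AT2G27190), from 24.9 ± 3.81 to 67.9 ± 17.8. Acid phosphatase genes as a set had adjusted p = 0.0154, and adjusted p = 0.265 with an estimated correlation. The former was 0.112 without KO replicate 2 at 200 µM and 0.0532 without KO replicate 3 at 200 µM. Iron storage genes rose as well, 3 of 5 over all genes and 5 adjusted over the list alone, with the ferritin genes FER1 (AT5G01600) from 71.4 ± 41.6 to 854 ± 509 and FER4 (AT2G40300) from 7.93 ± 4.16 to 58.8 ± 18.8. As a set, iron storage genes had adjusted p = 1.05e-07, and adjusted p = 0.259 with an estimated correlation. The 15 iron deficiency genes moved down as a set with a median log2 change of -0.90, 0 of them past the test over all genes and 6 down adjusted over the list alone. Iron deficiency genes as a set had adjusted p = 1.67e-06, and adjusted p = 0.309 with an estimated correlation. The largest rises outside these lists were in AT5G20790, a transmembrane protein, from 0.103 ± 0.179 to 98.9 ± 57, AT4G16563, an aspartyl protease, from 3.33 ± 1.63 to 88.4 ± 42, and AGP17 (AT2G23130), an arabinogalactan protein, from 10.9 ± 7.18 to 207 ± 102. AT1G23110 averaged 15.8 ± 12.5 at 0 µM and was listed at 0 at 200 µM. The largest falls were in HAI2 (AT1G07430), a protein phosphatase induced by abscisic acid (-2.1), the homeobox gene HB-12 (AT3G61890, -2.00), ORG1 (AT5G53450, -1.93), AT5G03230 (-1.94) and the heat shock factor gene HSFC1 (AT3G24520, -1.9). Salicylic acid and immunity genes had a median of -0.90. As a set, salicylic acid genes had adjusted p = 0.000374, and adjusted p = 0.4 with an estimated correlation. The median was -0.54 without KO replicate 1 at 200 µM and -0.6 without KO replicate 3 at 0 µM. The evening clock gene LUX (AT3G46640) rose by 1.34, from 40.9 ± 3.44 to 106 ± 16.7.

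In KO leaf 159 genes rose and 23 fell at 0 µM (2405 genes at unadjusted p under 0.05), and the adjusted p of the genes named for KO leaf lay between 0.000273 and 0.0465. The median of all genes shifted by 0.15, and with median-of-ratios scaling 116 rose and 26 fell. Without KO replicate 1 at 0 µM 55 genes passed, and without KO replicate 2 at 0 µM 74. The count was 80 with the libraries of the comparison's groups alone. PAP17, PAP12, SQD2, HAI2, HB-12, ORG1 and AT5G03230 each lost the call without at least 1 of KO replicates 1, 2 and 3 at either Pi level. For PAP17 adjusted p reached 0.15, for PAP12 0.131, for SQD2 0.124, for HAI2 0.157, for HB-12 0.147, for ORG1 0.0694, and for AT5G03230 0.258.

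In OE leaf the largest rises were in genes outside the fixed lists. EXO (AT4G08950) and PHI-1 (AT1G35140), of the phosphate-responsive exordium family, rose by 5.06 ± 0.74 and 4.33 ± 0.66, from 2.17 ± 1.35 to 108 ± 54 and from 1.69 ± 1.39 to 49.3 ± 19.2 FPKM. The xyloglucan endotransglucosylase genes TCH4 (AT5G57560) and XTH33 (AT1G10550) rose by 4.83 and 4.08, and AT4G16563 from 3.29 ± 1.37 to 97.9 ± 13.9. Of the Pi starvation genes 1 of 10 passed (5 adjusted over the list alone), namely SPX1, from 9.41 ± 2.57 to 40.5 ± 11.3. Pi starvation genes as a set had adjusted p = 3.38e-05, and adjusted p = 0.265 with an estimated correlation. Of the lipid genes 2 of 11 rose, MGD3 by 1.96 and SQD1 by 1.05 (3 adjusted over the list alone). As a set, lipid remodelling genes had adjusted p = 0.00645, and adjusted p = 0.69 with an estimated correlation. The former was 0.0697 without OE replicate 1 at 0 µM. FER3 (AT3G56090), a ferritin gene, rose by 2.02, the 1 of 5 iron storage genes past the test (2 adjusted over the list alone). Iron storage genes as a set had adjusted p = 0.0007, and adjusted p = 0.341 with an estimated correlation. DIN10 (AT5G20250), a raffinose synthase family gene induced in darkness, rose by 2.63, from 20.2 ± 3.36 to 131 ± 24, and LUX by 0.97. HSFC1, HAI2 and HB-12 fell by 2.27, 2.58 and 1.74. Cold, drought and abscisic acid genes had a median of -0.61, with 0 of 14 down past the test and 3 adjusted over the list alone. As a set, cold and drought genes had adjusted p = 9.84e-06, and adjusted p = 0.309 with an estimated correlation. Autophagy genes had a median of -0.42. Autophagy genes as a set had adjusted p = 2.51e-06, and adjusted p = 0.341 with an estimated correlation.

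In OE leaf 113 genes rose and 19 fell (1393 at unadjusted p under 0.05), with adjusted p of the genes named for OE leaf between 0.000136 and 0.0485. OE replicate 1 at 0 µM, a library with low long genes (-1.04), was 1 of the 6. The count was 36, 67 and 27 without OE replicates 1, 2 and 3 at 200 µM, and 47 and 33 without OE replicates 2 and 3 at 0 µM. It was 210 with the libraries of the comparison's groups alone. TCH4, XTH33, SPX1, MGD3, SQD1, FER3, DIN10, LUX, HAI2 and HB-12 each lost the call without at least 1 of OE replicates 1, 2 and 3 at either Pi level. For TCH4 adjusted p reached 0.0987, for XTH33 0.147, for SPX1 0.0994, for MGD3 0.225, for SQD1 0.192, for FER3 0.276, for DIN10 0.114, for LUX 0.0811, for HAI2 0.0604, and for HB-12 0.215.

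In WT leaf 1 gene passed (1026 at unadjusted p under 0.05): AT1G73390, which encodes a BRO1-like domain protein, rose by 1.61 ± 0.21 (adjusted p = 0.0153), from 8.63 ± 0.279 to 28.5 ± 2.75 FPKM. SPX1 averaged 32.7 ± 3.28 at 0 µM and 12.7 ± 8.97 at 200 µM, a log2 change of 1.5 that did not pass (adjusted p = 0.402). As sets, the Pi starvation genes moved up with a median of 0.67 and 0 of 10 past the test (2 adjusted over the list alone). As a set, Pi starvation genes had adjusted p = 0.00196, and adjusted p = 0.341 with an estimated correlation. The former was 0.168 without WT replicate 1 at 0 µM and 0.174 without WT replicate 3 at 200 µM. The median was 0.43 without WT replicate 2 at 0 µM. Lipid genes had a median of 0.29 and acid phosphatases of 0.27. Lipid remodelling genes as a set had adjusted p = 0.0253, and adjusted p = 0.823 with an estimated correlation. The former was 0.0646 without WT replicate 2 at 0 µM, 0.0759 without WT replicate 3 at 0 µM, 0.41 without WT replicate 2 at 200 µM and 0.0501 without WT replicate 3 at 200 µM. The median was 0.58 without WT replicate 1 at 200 µM. As a set, acid phosphatase genes had adjusted p = 0.0423, and adjusted p = 0.309 with an estimated correlation. The former was 0.349 without WT replicate 1 at 0 µM, 0.0549 without WT replicate 2 at 200 µM and 0.174 without WT replicate 3 at 200 µM. Anthocyanin and flavonoid genes moved down with a median of -1.43, 7 of 13 adjusted over the list alone, and iron deficiency genes with -0.54. Anthocyanin genes as a set had adjusted p = 9.79e-08, and adjusted p = 0.309 with an estimated correlation. The median was -0.78 without WT replicate 1 at 200 µM. As a set, iron deficiency genes had adjusted p = 0.00138, and adjusted p = 0.485 with an estimated correlation. WT replicate 1 at 0 µM and WT replicate 2 at 200 µM, both with low long genes (-0.88 and -1.25), were among these 6 libraries, and coding length and log2 change had a rank correlation of 0.42 across 12062 genes, which are not independent. Without WT replicate 1 at 0 µM 23 genes passed and without WT replicate 2 at 200 µM 3. AT1G73390 lost its call without WT replicates 2 and 3 at 0 µM and WT replicates 1 and 3 at 200 µM (adjusted p up to 0.144), which left 0 genes by limma in each case, with 738, 479, 1072 and 1194 at unadjusted p under 0.05. With the libraries of the comparison's groups alone 0 genes passed by limma too (743 at unadjusted p under 0.05). Over the 31 tested genes of the Pi starvation, lipid remodelling and acid phosphatase lists, WT replicate 1 at 200 µM stood apart: its mean log2 level was 3.88, against 3.75 to 3.78 in WT at 0 µM and 2.93 to 3.28 in the other 8 libraries at 200 µM.

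**Figure D3:**
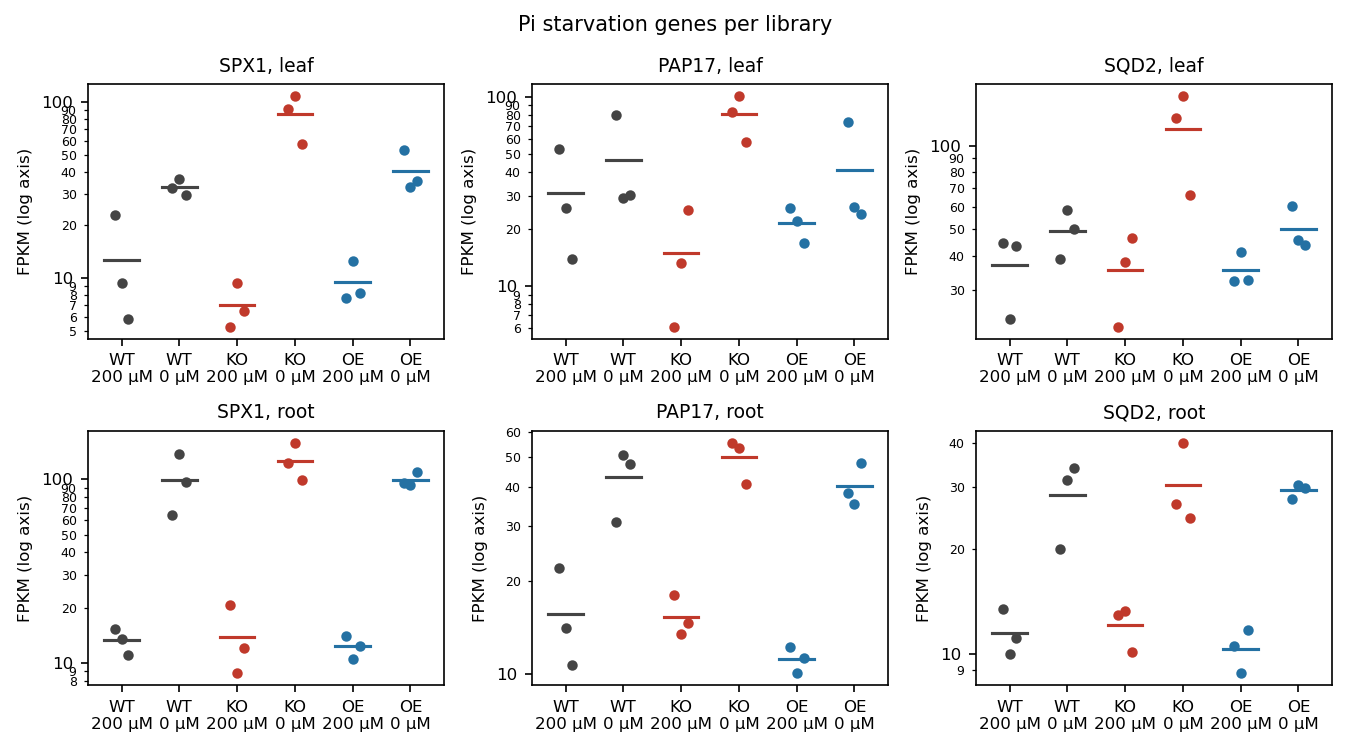
FPKM of SPX1, PAP17 and SQD2 in each library on a log axis, by genotype and Pi level in leaf and root, with a line at each group's mean of 3 libraries. SPX1 averaged 85.3 FPKM in KO leaf at 0 µM and 7.02 at 200 µM.

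Whether a line's leaf Pi response differed from that of WT was tested as an interaction. Higher and lower refer to the signed log2 change, not its size. Any difference from WT at 200 µM enters the interaction too. AT4G16563 had a higher response than WT in both lines, by 5.2 ± 0.61 in KO (adjusted p = 0.00297) and 5.41 ± 0.61 in OE (adjusted p = 0.000904), and AT5G54585, a hypothetical protein, a lower one, by -2.66 and -2.55. AT1G73480, an alpha/beta hydrolase, was lower in both, by -2.17 and -2.91, and LUX higher, by 1.6 and 1.24. In KO the cell wall genes FLA13 (AT5G44130) and EXL3 (AT5G51550) were higher by 3.64 and 3.68, and AT1G73390 lower by -1.68. In OE the arabinogalactan gene AGP7 (AT5G65390, 5.2), the expansin-like gene EXLA1 (AT3G45970, 4.43), DIN10 (3.65) and the nitrate transporter gene NRT1.1 (AT1G12110, 1.62) were higher, and P5CS1 (AT2G39800), of proline synthesis, lower (-2.62). No Pi starvation or lipid gene passed by itself in KO, where 4 and 6 were higher adjusted over the list alone, and as sets both were higher than in WT, with medians of 0.93 and 1.19. Pi starvation genes as a set had adjusted p = 0.00159, and adjusted p = 0.341 with an estimated correlation. As a set, lipid remodelling genes had adjusted p = 0.00194, and adjusted p = 0.647 with an estimated correlation. The WT response here includes WT replicate 1 at 200 µM, whose Pi genes stood at the level of 0 µM (3.88), and without it the medians were 0.79 and 1.00. Anthocyanin genes were higher as a set in both lines, by a median of 1.80 in KO and 1.59 in OE. Anthocyanin genes as a set had adjusted p = 1.67e-06 in KO and 8.32e-05 in OE, and adjusted p = 0.341 and 0.469 with an estimated correlation. The median was 0.93 in OE without WT replicate 1 at 200 µM.

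In all, 18 genes had a higher and 3 a lower Pi response in KO leaf than in WT leaf (1527 at unadjusted p under 0.05), and in OE leaf 45 had a higher and 13 a lower response (1358). The median shift for KO was 0.12, and with median-of-ratios scaling 9 were higher and 5 lower. With the libraries of the comparison's groups alone 0 genes passed by limma in KO (1183 at unadjusted p under 0.05), which ended each KO call named here, AT4G16563 and FLA13 included. The KO count was 35 without KO replicate 1 at 200 µM, 7 and 13 without KO replicates 1 and 2 at 0 µM, 45 and 12 without WT replicates 2 and 3 at 0 µM and 11 without WT replicate 3 at 200 µM. For OE it was 18, 29 and 18 without OE replicates 1, 2 and 3 at 200 µM, 22 and 13 without OE replicates 2 and 3 at 0 µM, 25, 91 and 36 without WT replicates 1, 2 and 3 at 0 µM, and 31 and 20 without WT replicates 1 and 2 at 200 µM. In KO, EXL3, LUX, AT1G73390 and AT1G73480 lost the call without at least 1 of KO replicates 1, 2 and 3 at either Pi level, WT replicates 1 and 3 at 0 µM and WT replicates 1, 2 and 3 at 200 µM. For EXL3 adjusted p reached 0.158, for LUX 0.0536, for AT1G73390 0.0995, and for AT1G73480 0.0536. In OE, AGP7, EXLA1, NRT1.1, DIN10, LUX and P5CS1 did so without at least 1 of OE replicates 1, 2 and 3 at either Pi level, WT replicates 1 and 3 at 0 µM and WT replicates 1, 2 and 3 at 200 µM. For AGP7 adjusted p reached 0.11, for EXLA1 0.0846, for NRT1.1 0.11, for DIN10 0.109, for LUX 0.14, and for P5CS1 0.0647.

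In roots the Pi response of WT held the known Pi starvation genes. IPS1 (AT3G09922), a noncoding RNA induced by Pi starvation, rose by 4.93 ± 0.61, from 0.24 ± 0.208 to 38.7 ± 15.3 FPKM, and G3Pp1 (AT3G47420), a putative glycerol-3-phosphate transporter, by 3.57 ± 0.25, from 5.65 ± 1.55 to 79.3 ± 23.3. SPX1 rose from 13.3 ± 2.07 to 99.2 ± 36.7, the Pi transporter gene PHT1;4 (AT2G38940) from 6.34 ± 1.27 to 24.6 ± 6.51 and AT5G20790 from 0.947 ± 0.452 to 31.8 ± 23.5. Of the Pi starvation list 10 of 17 rose and 1 fell (12 and 1 adjusted over the list alone), the faller being G3Pp2 (AT4G25220), a homologue of G3Pp1 (-1.29). As a set, Pi starvation genes had adjusted p = 9.08e-13, and adjusted p = 0.0573 with an estimated correlation. Lipid remodelling genes rose in 4 of 13 cases (6 adjusted over the list alone), among them the phospholipase gene NPC4 (AT3G03530), from 5.93 ± 1.04 to 24.7 ± 4.07, the glycerophosphodiester phosphodiesterase gene GDPD1 (AT3G02040, 1.11) and SQD2 (1.21). Lipid remodelling genes as a set had adjusted p = 2.14e-05, and adjusted p = 0.102 with an estimated correlation. The acid phosphatase genes PAP17 (1.43) and PAP1 (AT1G13750, 1.09) were among 4 of 13 that rose (8 adjusted over the list alone). As a set, acid phosphatase genes had adjusted p = 8.3e-05, and adjusted p = 0.0973 with an estimated correlation. Iron deficiency genes fell in 3 of 26 cases (6 adjusted over the list alone): the iron-responsive peptide gene IMA1 (AT1G47400) was listed at 0 at 0 µM against 24.8 ± 22.6, IMA2 (AT1G47395) changed by -3.98 and the transcription factor gene BHLH100 (AT2G41240) by -2.34. Iron deficiency genes as a set had adjusted p = 2.6e-05, and adjusted p = 0.295 with an estimated correlation. The former was 0.0803 without WT replicate 1 at 200 µM. IMA1 and IMA2 share 20.3% of their 31-base words with each other, so their split is uncertain. Of the regulators of Pi signalling 1 of 16 fell, WRKY75 (AT5G13080) by 1.62, and the list did not pass (adjusted p = 0.221). Senescence and starvation genes moved down, 2 of 11 past the test (2 adjusted over the list alone), the dark-induced gene SEN1 (AT4G35770) by -1.9 and the transcription factor gene NAP (AT1G69490) by -1.65. As a set, senescence genes had adjusted p = 0.00346, and adjusted p = 0.102 with an estimated correlation. Heat shock genes moved down with 1 of 14 past the test, MBF1C (AT3G24500, -1.1), and 2 adjusted over the list alone. Heat shock genes as a set had adjusted p = 0.000123, and adjusted p = 0.215 with an estimated correlation. Among root tissue markers the suberin genes CYP86A1 (AT5G58860, 0.88) and GPAT5 (AT3G11430, 0.77) rose, 2 of 22 (2 adjusted over the list alone), and the list did not pass (adjusted p = 0.176). The ammonium transporter gene AMT1;2 (AT1G64780, 1.23) and the flavonoid gene CHI (AT3G55120, 1.42) rose singly, and neither the nitrogen uptake list (adjusted p = 0.0833) nor the anthocyanin list (adjusted p = 0.112) passed.

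In WT root 213 genes rose and 163 fell (3851 at unadjusted p under 0.05), and adjusted p of the genes named for WT root lay between 5.36e-07 and 0.0485. The median of all genes shifted by 0.13, and with median-of-ratios scaling 77 rose and 265 fell. Long genes moved with this comparison: median coding length was 1575 bases among risers, 582 among fallers and 1131 among all genes, and WT replicates 2 and 3 at 200 µM had the lowest long-gene levels in root, at -1.23 and -0.47. Without WT replicate 2 at 200 µM 114 rose and 109 fell, 156 of them shared with the call on all libraries. The count was 1824 and 96 without WT replicates 1 and 3 at 200 µM, and 37 and 30 without WT replicates 2 and 3 at 0 µM. With the libraries of the comparison's groups alone 8 genes passed, among them SPX1, IPS1, AT5G20790, G3Pp1 and NPC4, and the other genes named for WT root lost the call. SPX1, IPS1, AT5G20790, G3Pp1, NPC4 and PHT1;4 passed with any 1 library left out. The other genes named for WT root each lost the call without at least 1 of WT replicates 1, 2 and 3 at either Pi level. For PAP17 adjusted p reached 0.0614, for PAP1 0.135, for SQD2 0.0753, for GDPD1 0.0682, for AMT1;2 0.0886, for CHI 0.0753, for CYP86A1 0.0614, for GPAT5 0.169, for IMA1 0.0567, for IMA2 0.18, for BHLH100 0.202, for WRKY75 0.0718, for SEN1 0.143, for NAP 0.132, for G3Pp2 0.226, and for MBF1C 0.11.

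In KO roots AT5G20790 rose by 5.03 ± 0.45, from 1.35 ± 0.619 to 78.8 ± 34.6 FPKM, G3Pp1 by 3.89 ± 0.25, from 6.57 ± 2.05 to 110.0 ± 22.2, and SPX1 from 13.9 ± 6.2 to 127 ± 30.1. IPS1 (4.4), SPX3 (AT2G45130, 2.26), PHT1;4 (1.85) and PS2 (AT1G73010), annotated as an inorganic pyrophosphatase (2.1), rose too, and AT1G08165 reached 15 ± 4.12 from a group listed at 0. Of the Pi starvation list 11 of 17 rose (11 up and 1 down adjusted over the list alone). As a set, Pi starvation genes had adjusted p = 2.34e-12, and adjusted p = 0.0573 with an estimated correlation. In the lipid list 5 of 13 rose (5 adjusted over the list alone), including GDPD1 from 32.8 ± 3.24 to 134 ± 41.3, SQD1 from 12.5 ± 2.05 to 38.1 ± 4.37 and SQD2 (1.24). Lipid remodelling genes as a set had adjusted p = 4.97e-06, and adjusted p = 0.0973 with an estimated correlation. The acid phosphatase list had 6 risers of 13 (7 adjusted over the list alone), with PAP17 from 15.3 ± 2.33 to 50 ± 7.93. As a set, acid phosphatase genes had adjusted p = 4.97e-06, and adjusted p = 0.0573 with an estimated correlation. Flavonoid genes rose in 7 of 15 cases (11 adjusted over the list alone), among them chalcone synthase CHS (AT5G13930), from 135 ± 39.6 to 493 ± 67.8, and F3H (AT3G51240), from 23.5 ± 7.09 to 66.7 ± 8.17. Anthocyanin genes as a set had adjusted p = 8.17e-09, and adjusted p = 0.173 with an estimated correlation. Iron deficiency genes fell in 7 of 26 cases (14 adjusted over the list alone), among them the coumarin synthesis genes S8H (AT3G12900), from 88.8 ± 32 to 12.1 ± 7.02, and CYP82C4 (AT4G31940), from 51.7 ± 22.9 to 8.08 ± 3.62, and the peptide genes IMA1 (-3.23) and IMA3 (AT2G30766, -3.67). As a set, iron deficiency genes had adjusted p = 2.59e-11, and adjusted p = 0.0979 with an estimated correlation. CYP82C4 shares 25.6% of its 31-base words with a neighbouring family member and is uncertain to that extent. FER1 rose by 1.01, 1 of 4 iron storage genes (2 adjusted over the list alone). Iron storage genes as a set had adjusted p = 0.0163, and adjusted p = 0.308 with an estimated correlation. The former was 0.0575 without KO replicate 2 at 200 µM. PHO2 (AT2G33770), a ubiquitin-conjugating enzyme of Pi signalling, fell from 140.4 ± 23.4 to 56.6 ± 7.07 and the zinc finger gene ZAT6 (AT5G04340) changed by -1.39, 3 of 16 Pi signalling regulators in all (4 adjusted over the list alone), and this list did not pass (adjusted p = 0.0629). Senescence and starvation genes fell in 4 of 11 cases (7 adjusted over the list alone), NAP from 128 ± 30.7 to 29.9 ± 19.5 and DIN10 from 566 ± 19.1 to 225 ± 46, and the list held both ways (adjusted p = 2.81e-06, and adjusted p = 0.0377 with an estimated correlation). The autophagy gene ATG8B fell from 75.7 ± 2.72 to 34.1 ± 6.09, 1 of 22 in its list (2 adjusted over the list alone). As a set, autophagy genes had adjusted p = 0.000164, and adjusted p = 0.295 with an estimated correlation. Cell cycle genes moved up, 1 of 18 past the test, the B-type cyclin gene CYCB2;4 (AT1G76310, 0.87), and 9 adjusted over the list alone. Cell cycle genes as a set had adjusted p = 4.51e-05, and adjusted p = 0.274 with an estimated correlation. GLYI7 (AT1G80160), a glyoxalase family gene, fell from 108 ± 5.1 to 15.3 ± 11.7.

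Several lists in KO root moved little. Proteasome subunit genes had a median of 0.21 and jasmonate genes of -0.27. As a set, proteasome genes had adjusted p = 0.0247, and adjusted p = 0.68 with an estimated correlation. The former was 0.217 without KO replicate 2 at 200 µM and 0.159 without KO replicate 3 at 0 µM. Jasmonate genes as a set had adjusted p = 0.0294, and adjusted p = 0.472 with an estimated correlation. The former was 0.171 without KO replicate 3 at 200 µM, 0.0563 without KO replicate 1 at 0 µM and 0.218 without KO replicate 2 at 0 µM. The median was -0.4 without KO replicate 3 at 0 µM. The list of nitrogen regulators had 1 faller of 7, LBD37 (AT5G67420, -0.92), and did not pass (adjusted p = 0.0907). GORK (AT5G37500), a potassium channel gene, rose by 1.12, 1 of 17 in the potassium list, which did not pass (adjusted p = 0.905), and RFNR2 (AT1G30510) rose by 0.65 in the nitrogen uptake list, which did not either (adjusted p = 0.903). The clock genes RVE4 (AT5G02840, -0.92) and LNK2 (AT3G54500, -0.85, with 1 or more libraries overlapping) fell, and their list did not pass (adjusted p = 0.0629). In KO root 243 genes rose and 433 fell (3771 at unadjusted p under 0.05), with adjusted p of the genes named for KO root between 1.31e-07 and 0.0476. With median-of-ratios scaling 186 rose and 574 fell. KO replicates 1 and 2 at 0 µM were the shallowest libraries. The count was 384, 322 and 331 without KO replicates 1, 2 and 3 at 200 µM and 305 and 318 without KO replicates 1 and 3 at 0 µM. IMA1, IMA3, FER1, GORK, LBD37, CYCB2;4, RVE4, LNK2 and RFNR2 each lost the call without at least 1 of KO replicates 1, 2 and 3 at either Pi level. For IMA1 adjusted p reached 0.0845, for IMA3 0.154, for FER1 0.152, for GORK 0.123, for LBD37 0.117, for CYCB2;4 0.14, for RVE4 0.149, for LNK2 0.187, and for RFNR2 0.155.

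In OE root fewer genes passed, 21 up and 24 down (1136 at unadjusted p under 0.05), with the Pi starvation genes again at the top. AT5G20790 rose by 3.87 ± 0.45, from 1.68 ± 1.27 to 35.3 ± 6.1 FPKM, SPX1 by 2.91 ± 0.28, from 12.4 ± 1.75 to 99.2 ± 8.98, G3Pp1 from 11.9 ± 1.69 to 83 ± 5.3 and IPS1 by 3.57. PHT1;4 (1.35), PAP17 (1.76), GDPD1 (1.57) and SQD2 (1.42) rose as well. The Pi starvation list had 8 risers of 17 (13 adjusted over the list alone), and its call held both ways (adjusted p = 1.39e-25, and adjusted p = 0.0278 with an estimated correlation). Lipid genes rose in 3 of 13 cases (4 adjusted over the list alone) and acid phosphatases in 1 of 13 (5 adjusted over the list alone). As a set, lipid remodelling genes had adjusted p = 3.03e-08, and adjusted p = 0.0559 with an estimated correlation. Acid phosphatase genes as a set had adjusted p = 1.38e-06, and adjusted p = 0.0559 with an estimated correlation. Among the largest falls, bZIP1 (AT5G49450), a transcription factor gene of low energy, fell by 2.1, the dark-induced genes SEN1 and DIN2 (AT3G60140) by 2.24 and 2.03, and NAP by 1.85. The senescence and starvation list had 3 fallers of 11 (4 adjusted over the list alone), and its call held both ways (adjusted p = 8.32e-06, and adjusted p = 0.0393 with an estimated correlation). The defensin-like gene PDF1.4 (AT1G19610) fell by 2.93, the threonine aldolase gene THA1 (AT1G08630) by 2.09 and WRKY75 by 1.44. Adjusted p of the genes named for OE root lay between 4.54e-05 and 0.0491. The count was 11, 13 and 19 without OE replicates 1, 2 and 3 at 200 µM and 14 and 12 without OE replicates 2 and 3 at 0 µM. It was 23 with the libraries of the comparison's groups alone. SQD2, IPS1, PHT1;4, PDF1.4, SEN1, bZIP1, THA1, DIN2, NAP and WRKY75 each lost the call without at least 1 of OE replicates 1, 2 and 3 at either Pi level. For SQD2 adjusted p reached 0.0515, for IPS1 0.102, for PHT1;4 0.189, for PDF1.4 0.0803, for SEN1 0.245, for bZIP1 0.0691, for THA1 0.212, for DIN2 0.26, for NAP 0.292, and for WRKY75 0.306.

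**Figure D4:**
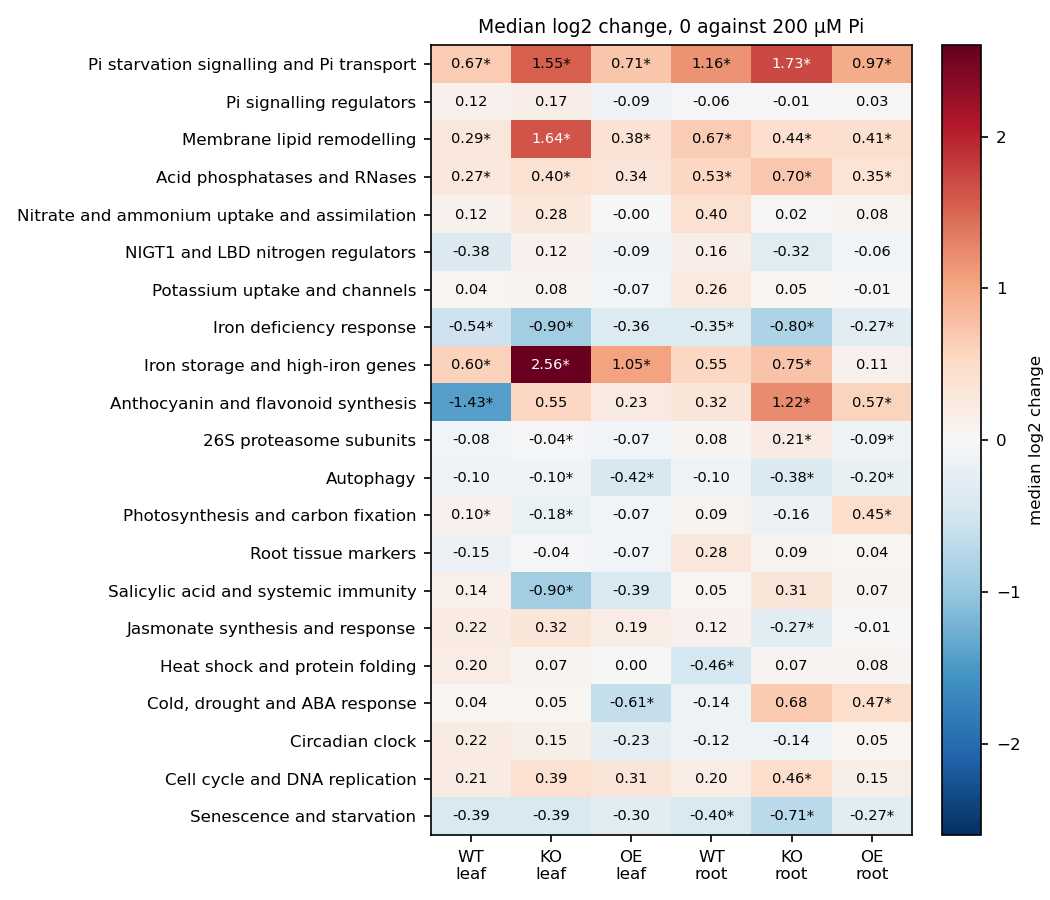
Median log2 change at 0 µM against 200 µM Pi of 21 gene lists (lines) in the 6 genotype and organ settings (columns), with an asterisk where camera with a preset correlation gave an adjusted p under 0.05. The Pi starvation list carries an asterisk in all 6 settings, with medians from 0.67 in WT leaf to 1.73 in KO root, and with an estimated correlation only OE root passed (adjusted p = 0.0278; 0.0573 in WT and KO root and 0.259 to 0.341 in leaf).

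In root 0 genes passed limma's test of a difference in Pi response from WT, in KO (2245 at unadjusted p under 0.05) or in OE (923). Both median-of-ratios scaling and voom on recovered reads also gave 0 in each line. Without WT replicate 1 at 200 µM, 158 genes passed in KO and 4 in OE. As sets, heat shock genes had a higher Pi response than in WT in both lines, with medians of 0.55 in KO and 0.43 in OE. As a set, heat shock genes had adjusted p = 8.3e-05 in KO and 3.32e-05 in OE, and adjusted p = 0.208 and 0.173 with an estimated correlation. The median was 0.9 in KO without WT replicate 2 at 200 µM, 0.36 in KO without WT replicate 3 at 200 µM and 0.23 in OE without WT replicate 3 at 200 µM. So did cold, drought and abscisic acid genes, with 0.67 in KO and 0.81 in OE. Cold and drought genes as a set had adjusted p = 0.00159 in KO and 1.88e-06 in OE, and adjusted p = 0.393 and 0.173 with an estimated correlation. The median was 0.44 in KO without WT replicate 3 at 200 µM and 0.5 in OE without WT replicate 3 at 200 µM. Photosynthesis genes, markers of green tissue, also lay higher in OE, with 0.31. As a set, photosynthesis genes had adjusted p = 1.48e-05, and adjusted p = 0.68 with an estimated correlation. The former was 0.97 without WT replicate 2 at 0 µM and 0.174 without OE replicate 3 at 200 µM. The median was 0.49 without WT replicate 1 at 200 µM, 0.1 without WT replicate 3 at 200 µM, 0.61 without WT replicate 1 at 0 µM, 0.52 without WT replicate 3 at 0 µM, 0.56 without OE replicate 2 at 200 µM and 0.2 without OE replicate 3 at 0 µM. Anthocyanin genes were higher in KO, with a median of 0.93 and 2 of 15 adjusted over the list alone. Anthocyanin genes as a set had adjusted p = 1.48e-05, and adjusted p = 0.308 with an estimated correlation. The median was 0.6 without WT replicate 2 at 0 µM.

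The genes that responded to Pi were compared between genotypes and organs with 2-sided Fisher's exact tests, 34 in all with Benjamini-Hochberg adjustment. Genes are not independent, so adjusted p (8.24e-14 or less here) does not measure replication over plants. In leaf 67 genes rose in both KO and OE (1.09 expected if independent), among them SPX1, MGD3, SQD1 and AT4G16563. Another 10 fell in both, among them HSFC1, HAI2 and HB-12. In root 38 genes rose and 100 fell in both WT and KO. The counts were 19 and 20 in WT and OE, and 19 and 22 in KO and OE. Between organs, 19 genes rose in both leaf and root of KO.

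Leaves of the lines were set against WT leaves at each Pi level to find what differed by genotype. At 200 µM both lines had lower levels of the same group of genes. AT4G16563 stood at 3.33 ± 1.63 FPKM in KO and 3.29 ± 1.37 in OE against 78.9 ± 15.2 in WT (log2 changes -4.27 ± 0.43 and -4.25 ± 0.43). DIN10 stood at 23 ± 16.9 and 20.2 ± 3.36 against 227 ± 203, and NRT1.1, a nitrate transporter and sensor gene, at 32.9 ± 3.23 and 27.4 ± 1.13 against 84.6 ± 9.71. P5CS1 was higher, at 353 ± 11.4 and 439.9 ± 77.7 against 105 ± 44.6. AGP17 had a log2 change of -3.24 in KO, and LRX3 (AT4G13340), a leucine-rich repeat extensin, and AGP7 had -3.53 and -3.52 in OE. Anthocyanin and flavonoid genes were lower in both, 2 of 13 in KO (1 higher and 7 lower adjusted over the list alone) and 3 in OE (8 adjusted over the list alone). As a set, anthocyanin genes had adjusted p = 2.81e-05 in KO and 2.54e-10 in OE, and adjusted p = 0.4 and 0.265 with an estimated correlation. LDOX (AT4G22880), which makes anthocyanidins, changed by -2.54 in KO and -2.89 in OE, the glycosyltransferase gene UGT75C1 (AT4G14090) by -2.1 in KO and CHS by -2.79 in OE. Iron storage genes were lower in KO, 2 of 5 (4 adjusted over the list alone), with FER1 at -2.61 and FER4 at -1.98. Iron storage genes as a set had adjusted p = 0.000144, and adjusted p = 0.309 with an estimated correlation. Clock genes moved up as a set in KO, with a median of 0.62, and in OE, with 0.35, while single clock genes went both ways in KO: LUX changed by -1.29 and PRR9 (AT2G46790) by 1.77. As a set, clock genes had adjusted p = 0.00168 in KO and 0.0273 in OE, and adjusted p = 0.33 and 0.526 with an estimated correlation. The former was 0.0603 in KO without KO replicate 1 at 200 µM, 0.168 in OE without OE replicate 2 at 200 µM and 0.216 in OE without WT replicate 2 at 200 µM. The median was 0.58 in OE without WT replicate 1 at 200 µM. PRR9 shares 31.8% of its 31-base words with another gene and is uncertain to that extent. Cold, drought and abscisic acid genes were higher in OE with 1 of 14 past the test, P5CS1 (2 adjusted over the list alone), and salicylic acid genes in both lines, with medians of 0.62 in KO and 0.67 in OE. Cold and drought genes as a set had adjusted p = 0.000537, and adjusted p = 0.35 with an estimated correlation. As a set, salicylic acid genes had adjusted p = 0.00153 in KO and 0.00383 in OE, and adjusted p = 0.485 and 0.574 with an estimated correlation. The former was 0.422 in OE without OE replicate 3 at 200 µM and 0.0944 in OE without WT replicate 3 at 200 µM. The median was 1.06 in KO without KO replicate 3 at 200 µM.

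At 200 µM 18 genes were higher and 126 lower in KO leaf (2253 at unadjusted p under 0.05), and 10 higher and 53 lower in OE leaf (1341). The median shift in KO was -0.10, and with median-of-ratios scaling 28 were higher and 89 lower. With the libraries of the comparison's groups alone 1 was higher and 7 lower in KO, among them DOT1, MRD1, AT3G01345, AT4G16563 and AT2G21185, and the other genes named for KO lost the call. Both comparisons use WT replicate 1 at 200 µM, whose Pi genes lay at the level of 0 µM (3.88), and WT replicate 2 at 200 µM, whose long genes were low (-1.25), and KO uses KO replicate 1 at 200 µM, which had the most genes at 0. In both lines together 8 genes were higher and 44 lower, where 0.0109 and 0.405 would be shared by independent comparisons and 0 on average in 100 simulated sets of unchanged groups with a shared WT. The simulated sets varied each gene independently. They leave out shifts that many genes of a WT library share, so they do not test that source. At 0 µM 3 genes were higher and 3 lower in KO leaf (428 at unadjusted p under 0.05) and 3 higher and 2 lower in OE leaf (588), namely MRD1, AT3G01345, AT1G75945, AT2G21185 and CYP97B3 in both and DOT1 in KO. Without WT replicates 1 and 2 at 200 µM the KO count at 200 µM was 78 and 51, and without OE replicates 1, 2 and 3 at 200 µM the OE count was 32, 39 and 29. In KO, AGP17, FER1, FER4, LDOX, UGT75C1 and PRR9 lost the call without at least 1 of KO replicates 1 and 2 at 200 µM and WT replicates 1, 2 and 3 at 200 µM. For AGP17 adjusted p reached 0.0886, for FER1 0.154, for FER4 0.0837, for LDOX 0.0545, for UGT75C1 0.17, and for PRR9 0.19. In OE, LRX3, AGP7, DIN10, LDOX and CHS did so without at least 1 of OE and WT replicates 1, 2 and 3 at 200 µM. For LRX3 adjusted p reached 0.084, for AGP7 0.216, for DIN10 0.0509, for LDOX 0.0509, and for CHS 0.182. Adjusted p of the genes named for leaf of the lines at 200 µM lay between 1.45e-11 and 0.0465.

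In root few single genes differed by genotype beyond DOT1 and the 4 shared genes. AT5G41180, a leucine-rich repeat receptor-like kinase, was higher in OE at 200 µM, 17.1 ± 0.958 against 4.38 ± 0.777 FPKM (adjusted p = 0.0033), and at 0 µM in KO (1.47) and OE (1.34). The laccase gene LAC2 (AT2G29130) was lower in both lines at 0 µM, by -2.35 (adjusted p = 0.0147) and -2.41 (adjusted p = 0.0137), and in OE at 0 µM CYP82C4 was lower (-2.46) and CYP97B3 higher (1.37). As sets, iron deficiency genes were lower in OE at both Pi levels, with a median of -0.48 at 200 µM (4 of 26 adjusted over the list alone) and -0.33 at 0 µM, and in KO at 0 µM (-0.26). Iron deficiency genes as a set had adjusted p = 5.89e-09 in OE at 200 µM, 4.15e-06 in OE at 0 µM and 0.00396 in KO at 0 µM, and adjusted p = 0.142, 0.269 and 0.493 with an estimated correlation. The former was 0.0638 in KO at 0 µM without KO replicate 1 at 0 µM. The median was -0.25 in OE at 200 µM without WT replicate 1 at 200 µM, -0.77 in OE at 200 µM without WT replicate 2 at 200 µM, -0.16 in KO at 0 µM without WT replicate 2 at 0 µM and -0.41 in KO at 0 µM without WT replicate 3 at 0 µM. Anthocyanin genes were higher in OE at 200 µM (0.91) and at 0 µM, where 12 of 15 passed adjusted over the list alone and 0 over all genes, and in KO at 0 µM (0.71). As a set, anthocyanin genes had adjusted p = 3.26e-06 in OE at 200 µM, 9.08e-13 in OE at 0 µM and 8.69e-08 in KO at 0 µM, and adjusted p = 0.274, 0.0973 and 0.215 with an estimated correlation. The median was 0.59 in OE at 200 µM without WT replicate 1 at 200 µM and 0.44 in KO at 0 µM without WT replicate 2 at 0 µM. Nitrogen uptake genes were higher in KO at 200 µM with a median of 0.24 (2 of 25 adjusted over the list alone), and the nitrogen regulator list was lower at 0 µM in KO (-0.41) and OE (-0.37). Nitrogen uptake genes as a set had adjusted p = 2.25e-05, and adjusted p = 0.342 with an estimated correlation. The median was 0.38 without WT replicate 1 at 200 µM and 0.37 without KO replicate 1 at 200 µM. As a set, nitrogen regulator genes had adjusted p = 0.000838 in KO and 0.000969 in OE, and adjusted p = 0.269 and 0.269 with an estimated correlation. Photosynthesis genes were higher in OE at 0 µM, 34 of 41 adjusted over the list alone and 0 over all genes, with a median of 0.96. Photosynthesis genes as a set had adjusted p = 2.31e-28, and adjusted p = 0.215 with an estimated correlation. The median was 0.54 without WT replicate 2 at 0 µM. At 200 µM their medians were 0.42 in KO and 0.71 in OE. As a set, photosynthesis genes had adjusted p = 9.72e-05 in KO and 1.38e-06 in OE, and adjusted p = 0.717 and 0.64 with an estimated correlation. The former was 0.204 in KO without WT replicate 1 at 200 µM.

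At 200 µM 2 genes were higher and 4 lower in KO root (2507 at unadjusted p under 0.05) and 4 higher and 4 lower in OE root (2367), with a median shift of 0.13 in OE. At 0 µM 3 were higher and 7 lower in KO root (2338) and 4 higher and 9 lower in OE root (1366). Coding length and log2 change had rank correlations of 0.51 in KO and 0.47 in OE at 200 µM across 15032 genes, which are not independent, and WT replicate 2 at 200 µM, with low long genes (-1.23), is in both. Without WT replicate 1 at 200 µM 923 genes passed in KO and 362 in OE at 200 µM. At 0 µM the KO count was 17 with the groups of the comparison alone, 6 and 5 without WT replicates 1 and 3 and 29 without KO replicate 2, and the OE count was 5, 8 and 7 without WT replicates 1, 2 and 3 and 5 and 6 without OE replicates 2 and 3. LAC2 and AT5G41180 lost the call in KO at 0 µM without at least 1 of KO replicates 1 and 3 and WT replicates 1, 2 and 3. For LAC2 adjusted p reached 0.109 and for AT5G41180 0.146. LAC2, AT5G41180, CYP82C4 and CYP97B3 lost it in OE at 0 µM without at least 1 of OE and WT replicates 1, 2 and 3. For LAC2 adjusted p reached 0.0957, for AT5G41180 0.351, for CYP82C4 0.351, and for CYP97B3 0.166.

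**Figure D5:**
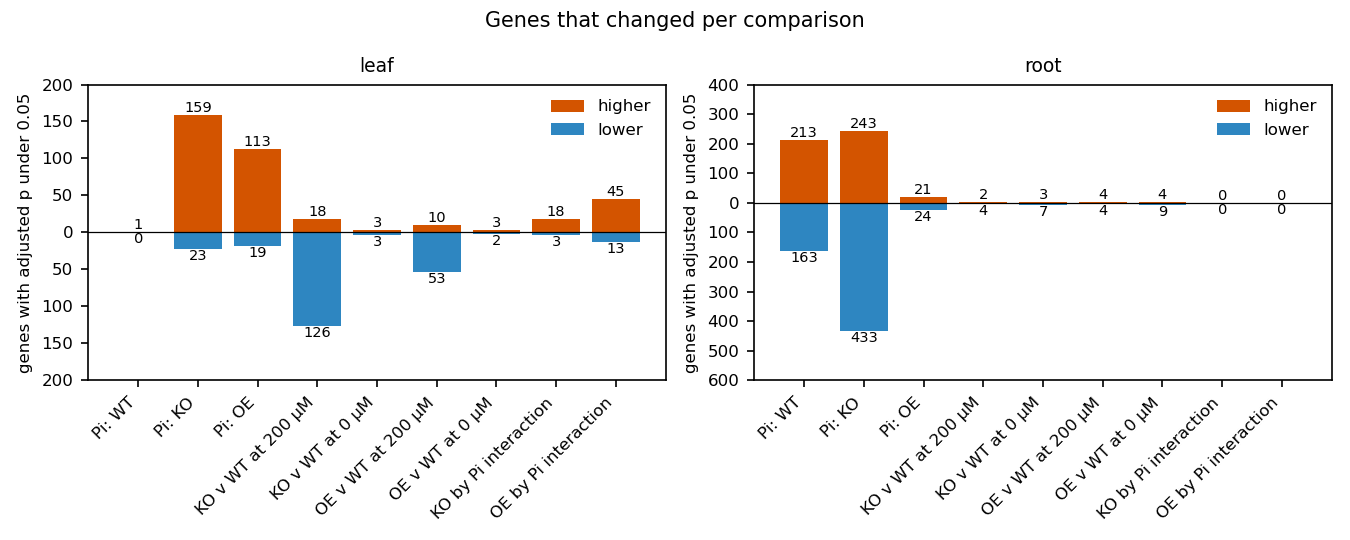
Number of genes higher (upward bars) and lower (downward bars) at an adjusted p under 0.05 in each of the 18 comparisons in leaf and root. The most genes passed in the Pi response of KO root, 243 higher and 433 lower, and 0 in the interactions in root.

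The deposited table also holds the authors' own adjusted p for each Pi response. Below 0.05 it held 30 genes in WT leaf, 615 in KO leaf, 525 in OE leaf, 250 in WT root, 1269 in KO root and 201 in OE root. Of the genes that passed here, 1 of 1, 159 of 182, 130 of 132, 166 of 376, 572 of 676 and 45 of 45 were among the authors' genes. The shared genes matched in direction, which lends no support, since both use the same values per library. For each gene named as changed in a Pi response or a line comparison, except LNK2, the 3 libraries of each group did not overlap those of the other. Chance gives this for 10% of unselected genes with 3 against 3, no baseline for genes that already passed a test on the same libraries. For the largest changes lack of overlap was also a condition of being named. It supports no named gene.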

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

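Of the tests of explanations in this part, all but the search for reads shared between similar genes and the splits of the libraries were chosen after the results were seen. The Pi response of leaf differed from that of WT in 21 genes in KO and in 58 in OE, by a test of the difference itself. Without a single library these counts ran from 7 to 45 in KO and from 13 to 91 in OE. With the comparison's groups alone the KO count was 0. The largest each way in KO (log2) were 5.20 in AT4G16563, 3.68 in EXL3, 3.64 in FLA13, -2.66 in AT5G54585, -2.17 in AT1G73480 and -1.68 in AT1G73390. In OE they were 5.41 in AT4G16563, 5.20 in AGP7, 4.43 in EXLA1, -2.91 in AT1G73480, -2.62 in P5CS1 and -2.55 in AT5G54585. These genes also differed from WT at 200 µM in the same line, and none passed at 0 µM. Both interactions use the same WT libraries, so a changed Pi response cannot be told apart from that difference. The effect of OE on DOT1 differed between leaf and root by 4.09 at 200 µM and 4.28 at 0 µM.

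In leaf at 200 µM, 52 genes differed from WT in the same direction in both lines, 44 lower and 8 higher. An exchange of the Pi labels between the WT leaf libraries is argued against, by the last of 3 measures tried: over 31 Pi genes the lowest WT library at 0 µM lay 0.473 (log2) above the highest KO or OE library at 200 µM, and 13 of the 15 Pi genes that rose in KO were higher at 0 µM in WT, with a median share of 0.271 of the change in KO. Over the 31 Pi genes, the library labelled WT replicate 1 at 200 µM alone stood at the level of 0 µM, at 3.88. The other 8 libraries at 200 µM lay between 2.93 and 3.28. Without WT replicate 1 at 200 µM, 40 genes were called in both lines, 35 of them among the 52. A source in a single library is argued against, by the last of 4 measures tried: over the genes called in both lines without a library, that library still stood at least 0.82 of the way from the other side to its own, WT or the lines, although as few as 26 of the 52 were called again (without OE replicate 3 at 200 µM). An hour of harvest that differed between WT and the lines cannot be told apart, by the last of 2 measures tried. The 16 clock genes moved more than 99.86% of 10000 random lists in KO and 98.24% in OE. With a library left out, KO stayed at 99.11% or more. OE fell to 79.31% without OE replicate 2 and 94.69% without WT replicate 2 at 200 µM, whose long genes were low (-1.25). A shared effect of both genotypes was not tested.

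MRD1, AT3G01345, AT1G75945 and AT2G21185 differed from WT in all 8 line comparisons, the same way in both lines. Reads shared with similar genes are argued against for coding sequence: MRD1, AT1G75945 and AT2G21185 share no 31-base word with another measured gene, and the 1 gene that shares 3 words with AT3G01345 carried a share of 0 of its difference with opposite sign. Chance in the shared WT libraries is argued against too, with 0 of 100 simulated draws giving 4 such genes. KO and OE differed by at most 0.214 of the gap to WT. Their choice required calls in both lines, so this cannot tell a WT stock unlike the lines' background from an effect of both genotypes. No tested neighbour of the 4 genes passed in any of the 8 comparisons. An effect of both genotypes stays open and was not tested.

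In WT root, genes that rose without Pi had longer coding sequences than those that fell, with a rank correlation of 0.484 between length and log2 change. A rise of long transcripts as strong as this in every genotype is argued against, since the correlations were 0.2 in KO and 0.246 in OE. A weaker rise shared by the genotypes was not excluded. Loss of long transcripts in WT replicate 2 at 200 µM is a candidate explanation, since the correlation was 0.176 without it, with 114 genes up and 109 down in place of 213 and 163. The genes SPX1, IPS1, G3Pp1, NPC4, PHT1;4 and AT5G20790 passed without that library too. A term for the long-gene level left 48 genes in all, 37 of them among those called without the term.

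The 6 libraries of a comparison of 3 against 3 make 10 splits, too few for a share under 0.05. In leaf, as many or more genes passed in 2 of the 10 splits for the Pi response of WT (1 gene, highest other split 61), in 1 for KO (182 and 1) and in 1 for OE (132 and 0). For the lines against WT in leaf it was 1 of 10 for KO at 200 µM (144 and 9), 1 for KO at 0 µM (6 and 0), 1 for OE at 200 µM (63 and 1) and 3 for OE at 0 µM (5 and 246). In root the number was 1 of 10 throughout: Pi response of WT (376 and 0), KO (676 and 0) and OE (45 and 0), and against WT KO at 200 µM (6 and 1), KO at 0 µM (10 and 0), OE at 200 µM (8 and 0) and OE at 0 µM (13 and 1). The interactions had 100 splits drawn. In leaf 3 of 100 gave as many genes for KO (21, highest other 110) and 3 of 100 for OE (58, highest other 1051), a share under 0.05. Because some of these splits called several times the real count, that share does not exclude chance. In root 100 of 100 did for KO (0, highest other 1) and 100 of 100 for OE (0, highest other 54), so chance was not excluded there either. Splits that call several times the real count point to a structure of the samples: the split with 61 set WT replicate 1 at 0 µM with WT replicates 1 and 2 at 200 µM, that with 246 set WT replicate 1 with OE replicates 1 and 3 at 0 µM, and that with 1051 held WT replicate 1 and OE replicates 1 and 3 at 0 µM on the same side, away from WT replicate 2 at 200 µM. These 3 splits place libraries with low long genes together, WT replicates 1 at 0 µM and 2 at 200 µM in the first and OE replicate 1 and WT replicate 1 at 0 µM in the others. In the split with 110, KO replicates 1 and 2 and WT replicate 2 stood together at 0 µM, and the split with 54 in root exchanged WT and OE at 0 µM alone, which turns the interaction into the mean difference between the lines.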

How the results depend on the processing

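Settings chosen after the data were seen are named under how the data were processed. Of 206 calls of named genes 0 reversed. The call was lost in 81 with the comparison's groups alone, 35 with the replicate block, 17 with 0.1 added, 45 without filter, 32 without trend, 16 with median-of-ratios scaling, 46 with voom, 27 of 87 without the farthest library, 24 with the long-gene term, and 422 of 1332 times with a library left out. The counts that moved by more than 1.5 times were as follows, and the cause was not tested except that the groups alone and a left-out library leave fewer samples. With the comparison's groups alone: WT leaf Pi 0 (from 1), KO leaf Pi 80 (182), OE leaf Pi 210 (132), KO leaf at 200 µM 8 (144), KO leaf interaction 0 (21), WT root Pi 8 (376), OE root Pi 23 (45), KO root at 0 µM 17 (10). With the replicate block, whose numbers do not pair the libraries, WT leaf Pi 2 and WT root Pi 162. Without filter: WT leaf Pi 2, OE leaf Pi 78, OE leaf interaction 30. Without trend: OE root Pi 29. With voom: KO leaf at 200 µM 95, OE leaf at 0 µM 3, WT root Pi 1084, KO root Pi 397, OE root at 200 µM 17. Without the farthest library: KO leaf interaction 35, WT root Pi 223. With the long-gene term: OE leaf Pi 248, KO leaf at 200 µM 311, OE leaf at 200 µM 131, KO leaf interaction 84, OE leaf interaction 134, WT root Pi 48.

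With 1 library left out the counts ran, in leaf, from 0 to 23 (WT Pi), 55 to 182 (KO Pi), 27 to 124 (OE Pi), 51 to 166 and 6 to 7 (KO at 200 and 0 µM), 29 to 53 and 5 to 6 (OE at 200 and 0 µM), 7 to 45 (KO interaction) and 13 to 91 (OE interaction). In root they ran from 30 to 1824 (WT Pi), 305 to 551 (KO Pi), 11 to 35 (OE Pi), 5 to 923 and 5 to 29 (KO at 200 and 0 µM), 6 to 362 and 5 to 11 (OE at 200 and 0 µM), 0 to 158 (KO interaction) and 0 to 4 (OE interaction). The libraries whose loss moved a count by more than 1.5 times are named beside that count in the results above. Of 126 list calls 57 were lost with a library left out, 30 in leaf and 27 in root, and 6 of these turned direction. Relative to other genes, their medians without 1 library ran from -0.659 to -0.013 (senescence, KO leaf at 0 µM), -0.046 to 0.731 (iron deficiency, OE leaf at 0 µM) and, for photosynthesis, -0.053 to 0.231 (WT leaf Pi), 0.018 to 0.336 (OE leaf at 200 µM), -0.281 to 0.415 (KO root at 0 µM) and -0.015 to 0.739 (OE root interaction). In the other settings 0 lists turned direction. In leaf 56 lists passed, 0 with an estimated correlation and 4 with fry, and in root 70, 3 and 19. The other list settings stayed within 1.5 times, and with them 3 to 12 of the 126 calls were lost. With 100 simulated genes per size, 3% of 2-fold differences in the KO leaf interaction and 7% in root were recovered, so most 2-fold differences in Pi response would be missed in these libraries. Smaller differences, other depths and other numbers of libraries were not simulated.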

Other observations

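All tests in this part that concern DOT1 as the targeted locus were chosen after the result was seen. Several fixed lists moved in ways not described above, each tested with camera and each lost with an estimated correlation. In leaf at 0 µM, KO lay above WT in lipid remodelling genes (median 1.13), 6 of 11 adjusted over the list alone and 0 over all genes, and in Pi starvation genes (median 0.54), 2 of 10 adjusted over the list alone. Lipid remodelling genes as a set had adjusted p = 2.54e-10, and adjusted p = 0.265 with an estimated correlation. As a set, Pi starvation genes had adjusted p = 2.81e-05, and adjusted p = 0.265 with an estimated correlation. The median was 0.36 without KO replicate 2 at 0 µM.

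In OE root at 0 µM against 200 µM Pi, cold, drought and abscisic acid genes (median 0.47) and anthocyanin genes (median 0.57) lay higher as sets, with 0 of 11 and 2 of 15 past the test over the list alone, and iron deficiency genes lower (median -0.27). Cold and drought genes as a set had adjusted p = 0.000543, and adjusted p = 0.33 with an estimated correlation. The median was 0.72 without OE replicate 1 at 200 µM and 0.29 without OE replicate 3 at 0 µM. As a set, anthocyanin genes had adjusted p = 4.97e-06, and adjusted p = 0.291 with an estimated correlation. The median was 0.26 without OE replicate 3 at 200 µM. Iron deficiency genes as a set had adjusted p = 6.38e-06, and adjusted p = 0.274 with an estimated correlation. Photosynthesis genes, markers of green tissue, lay higher with them (median 0.45), 0 of 41 past the test over the list alone. As a set, photosynthesis genes had adjusted p = 2.43e-06, and adjusted p = 0.645 with an estimated correlation. The former was 0.299 without OE replicate 3 at 200 µM. At 0 µM the roots of both lines lay above WT in cell cycle genes, KO with a median of 0.32 and OE with 0.21. Cell cycle genes as a set had adjusted p = 5.43e-05 in KO and 0.00396 in OE, and adjusted p = 0.274 and 0.472 with an estimated correlation. The median was 0.21 in KO without WT replicate 1 at 0 µM and 0.32 in OE without WT replicate 2 at 0 µM. Cold, drought and abscisic acid genes were higher in OE root at 0 µM, 3 of 11 adjusted over the list alone (median 0.76), and senescence genes lower in KO root (median -0.44) and OE root (median -0.31). As a set, cold and drought genes had adjusted p = 2.18e-07, and adjusted p = 0.138 with an estimated correlation. Senescence genes as a set had adjusted p = 0.0037 in KO and 0.000111 in OE, and adjusted p = 0.102 and 0.0559 with an estimated correlation. The median was -0.17 in OE without WT replicate 2 at 0 µM and -0.56 in OE without WT replicate 3 at 0 µM.

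DOT1 was hypothesised to be the locus targeted in both lines, since none of the 12 KO libraries reached the lowest WT library. In OE an overexpressed target would lie above WT. In leaf the lower of the log2 changes of OE against WT was 0.533 and did not pass, so the hypothesis cannot be told apart there, and in root the lower was -3.745 with a fall past the test at both Pi levels, which argues against an overexpressed DOT1 in root. Which locus carries the insertion or the transgene was not analysed here.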
